A study of Mus musculus with 12 samples.

How the data were processed

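Total RNA from the heart apex of adult male C57BL/6J mice was measured on 12 single-colour Agilent arrays, 3 in each of 4 groups of Nkx2-5 knock-in mice. Per the labels' protocols, RNA was extracted with a column kit, treated with DNase I and labelled with Cy3 as amplified cRNA. Each array holds 59305 spots of 55681 different probes for mouse transcripts. The labels do not say whether the replicates of a group came from separate animals, so the p-values given here measure the spread between these samples.

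Per the file headers, the scanner images were read with Agilent Feature Extraction 11.0.1.1 under protocol GE1_1100_Jul11, with a probe layout placed on the mm9 genome build. The deposited scanner files give intensity values per spot: the median pixel intensity, the intensity of the local background, and a processed intensity that Feature Extraction had corrected for background within each array. Per the file headers, none of these columns was normalized between arrays. A table of processed values of the same arrays, deposited by the authors, has a log2 scale by its range and by its match to the scanner values: its array medians lay between 6.89 and 6.94. Per the submitters' processing notes, Feature Extraction and limma were used, with no version given. That table's rank correlation with the processed intensity across probes lay between 0.961 and 0.998 per array, and its Pearson correlation with normexp and quantile normalized values lay between 0.996 and 0.997. Whether the authors applied exactly those steps is not stated, so the table was used as an alternative only.

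The log2 of the processed intensity was taken, spots that the scanner software had marked as outliers and control spots were left out, spots of the same probe were averaged, and each array's 75th percentile was subtracted. Levels below are therefore log2 values relative to that percentile, and differences are log2 folds. The files carry no gene names, so accessions were matched without their versions to a RefSeq gene table of assembly GRCm38.p6, which named 27235 of the 55681 probes. Because that assembly differs from the build of the layout, the table was used for names and for neighbouring genes, and none of its coordinates are given. A total of 96 probes with a missing value on some array were left out. A probe was tested where it was well above background on at least 3 of the 12 arrays (41591 probes), and a gene was read from its tested probe with the highest mean. This left 29795 genes or unnamed features, 17259 of them with a symbol. On control replicate 1 99.1% of spots were well above background, so it counted toward this filter for nearly every probe. AI593442 and Gdnf were well above background on the 3 control arrays only. They entered the test through the group in which they read high.

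Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with defaults) over all 12 arrays, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Each mutant line was compared with the control line, and each pair of mutant lines was compared directly, which gave 6 comparisons. Every adjusted p for a gene below comes from this fit unless another setting is named with it. For Nkx2-5 an exact two-sided permutation test of 3 against 3 arrays was added, whose smallest possible p is 0.1. Before the data were examined, 38 gene lists were fixed, 21 of pathways or functions and 17 of markers of cell types, with 941 symbols of which 880 were measured. The list tests of the 3 direct comparisons were added after the data were seen. Lists were tested with limma's camera with its preset correlation, adjusted over the 38 lists. Camera asks whether a list's genes stand apart from the other genes. It was run again with an estimated correlation between genes, and fry was run as well. The p of fry tests whether a list's genes move on balance in 1 direction and its mixed p whether they change in either direction, and neither compares the list with other genes. For the genes of a list, the count past the threshold adjusted over the list alone is given beside the count over all genes.

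Named genes follow a rule that was also fixed before the data were examined. The rule takes Nkx2-5 everywhere. In each comparison with the control line it takes up to 12 symbols that rose most and 12 that fell most past the threshold with no overlap between the groups, filled up to 10 by smallest p where fewer passed. For direct comparisons it takes up to 5 in each direction, or the 3 with the smallest p where none passed. Of each list it takes up to 4 members by smallest p. The value of 1 list member is not reported here. Where a probe was not well above background on any array of a group, the fold is given as a lower bound: the brighter group's mean was set against the dim group's mean of, per array, the higher of the probe's own value and the lowest value well above background. Where the dim group's own values lay above that lowest value, the bound equals the estimated fold, as for Abca4 in delta and Shisa6 in I183M. No bound allows for the spread between arrays. The bounds hold for the processed intensity only. Normexp adds its offset to every intensity, which by construction makes the folds of dim probes smaller.

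The array files number 2 slides. Slide 1 held the 3 control, the 3 I183M and 2 of the I183P arrays, and slide 2 held I183P replicate 3 and the 3 delta arrays. All control arrays lie on slide 1 and all delta arrays on slide 2, so these groups are joined only through the I183P arrays. Fits with the slide as a fixed or random block and within each slide were run as alternatives. The other alternatives were normexp background correction (offset 50) with quantile normalization, quantile normalization of the processed intensity, median scaling, the authors' table, no filter on dim probes, a filter on all 12 arrays, every probe fitted by itself, the replicate number as a block, only the 2 groups compared, eBayes with trend and robust, array weights, and each array left out in turn. The mean pixel intensity that normexp would usually start from is not in the files, so the median pixel intensity was used. After the data were seen, fits without control replicate 1 for the direct comparisons and shared changes or together with another choice, fits without the 3 arrays that had raised signal of dim probes, and fits with that signal as a covariate were added. In all fits that leave an array out, the remaining arrays of its group are assumed to vary like those of the other groups.

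The fits were tested on simulated data in which 100 of the 29795 genes were changed at each of 2 log2 folds and 1 list was shifted by 0.5. Each comparison was drawn 1 time, with independent values per gene and array, so no outlying array was simulated. Unchanged genes called for I183M, I183P and delta versus control numbered 0, 3 and 1, and 5, 4 and 1 without control replicate 1. With a log2 fold of 2, 38 of the 100 genes were recovered for delta versus control and 36 for I183P versus control, and with a log2 fold of 1, 4 of the 100 were recovered in either comparison. For I183M versus control the counts were 28 and 2. With control replicate 1 left out, 58, 55 and 52 of the 100 genes were recovered at a log2 fold of 2 for delta, I183P and I183M versus control. The number of arrays limits the precision of every value. Tables were handled with data.table (version 1.17.8), pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15, and plots were drawn with matplotlib 3.10.9.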

Results

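Nkx2-5 encodes a homeobox transcription factor of heart muscle. The series set out to compare the RNA of adult hearts of 3 knock-in lines with that of a control line. In the I183M and I183P lines an isoleucine of the protein is replaced by methionine or proline. The delta line carries a deletion allele of the gene, and the control line carries a knock-in that keeps the isoleucine. All labels give the altered allele together with a + allele. The mice were 15 weeks old, and each group holds 3 arrays. Between 51.2% and 75.2% of the 59305 spots were well above background on 11 of the 12 arrays, and no spot was saturated.

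Control replicate 1 stood apart from the other 11 arrays. On it 99.1% of spots were well above background, the median processed intensity was 602 against 34.8 to 92.5 on the others, and the 75th percentile was 1450 against 506.5 to 656.9. Probes that were dim elsewhere (13970 probes) had a median log2 intensity of 7.74 on that array. I183M replicate 1 (3.68) and delta replicate 2 (3.36) were the next highest, and the remaining arrays lay between 2.00 and 2.99. Across probes, the best rank correlation of control replicate 1 with any other array was 0.847, against 0.973 to 0.988 for the others. Against its 75th percentile the bright genes of heart muscle read low on this array: the median of the oxidative phosphorylation list was -1.27 there and between -0.07 and 0.19 on the other arrays, each gene set against its mean over all arrays. For this reason each comparison with the control line is also given without control replicate 1, a choice of this array made after the data were seen.

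**Figure D1:**
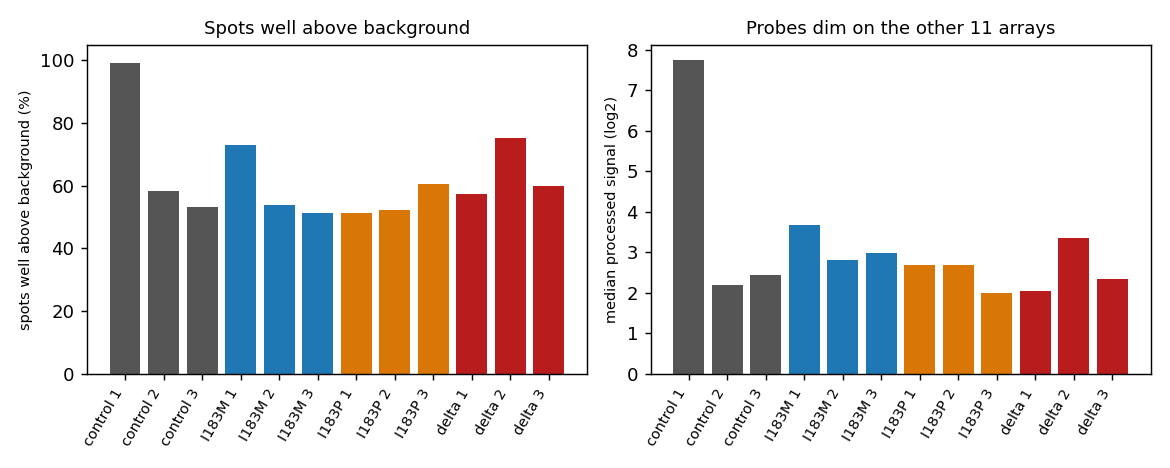
Share of spots well above background (left, percent) and median log2 processed intensity of the probes that were dim on the other arrays (right) for each of the 12 arrays, coloured by group. Control replicate 1 reads 99.1% and 7.74, and the other arrays read 51.2% to 75.2% and 2.00 to 3.68.

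Nkx2-5 itself, read by 1 probe for NM_008700 on chromosome 17 that was well above background on all 12 arrays, was at 4.04 ± 0.80 (SD, n = 3) in the control line, 4.57 ± 0.05 in I183M, 4.60 ± 0.13 in I183P and 3.83 ± 0.09 in delta. The 3 delta arrays read 3.77, 3.79 and 3.92, below all I183M and I183P arrays (4.51 to 4.74) and below control replicates 2 and 3 (4.45 and 4.56), while control replicate 1 read 3.12. The log2 folds against control were 0.53, 0.56 and -0.22 (SE 0.34) for I183M, I183P and delta, and none passed (adjusted p 0.879, 0.563 and 0.866, exact permutation p 0.2, 0.3 and 0.8, n = 3). The log2 fold of delta was -0.75 against I183M and -0.77 against I183P, a ratio of 0.595 and 0.585, with adjusted p 1 in both, and the exact permutation p was 0.1, the smallest that 3 against 3 allows. With control replicate 1 left out, delta versus control was -0.68 (SE 0.11, adjusted p 0.0647), a ratio of 0.625, and the folds of I183M and I183P were 0.07 and 0.09. Delta versus I183M and delta versus I183P do not hold that array but share its spread in the fit. With it left out of the shared fit their SE was 0.097 (0.339 with all arrays), with adjusted p 0.0564 and 0.0729. Without control replicate 3 the fold of delta versus control was 0.04 (adjusted p 0.925). With normexp and quantile normalization, control replicate 1 lay with its group (control 13.57 ± 0.04, delta 12.84 ± 0.06), and delta versus control passed at -0.72 (adjusted p 0.0286, between 0.0139 and 1 over all alternatives), a ratio of 0.605. On that scale delta was also lower than I183M (-0.85, adjusted p 0.0212) and I183P (-0.83, adjusted p 0.0327). The folds of delta with the slide as a block were -0.09 against control, -0.62 against I183M and -0.69 against I183P (adjusted p 1 in each), and within slide 2 the last was -0.69. The position of the probe within the deleted part of the gene is not given in the files.

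**Figure D2:**
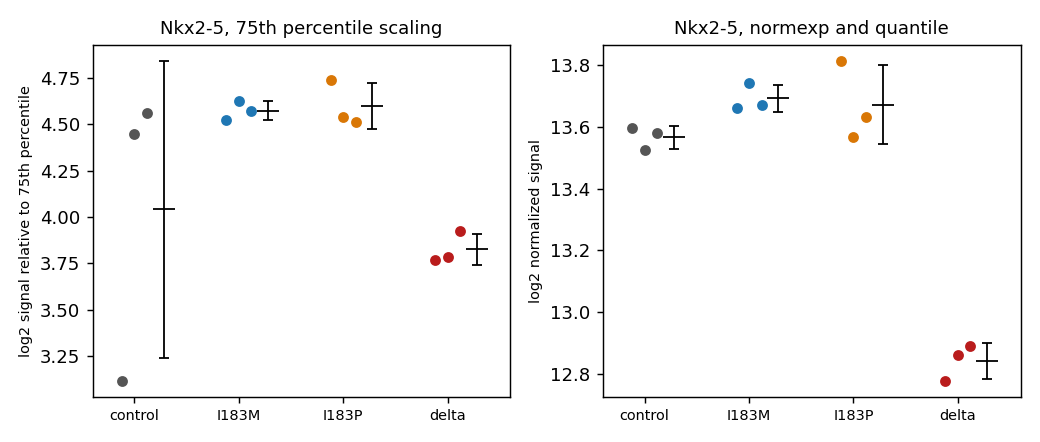
Nkx2-5 signal on each array (points) with the mean and SD of each group of 3 (bars), as log2 relative to the 75th percentile (left) and after normexp and quantile normalization (right, log2). On the right the delta mean is 12.84 and the control mean 13.57, while on the left control replicate 1 reads 3.12.

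I183M versus control compared hearts with the methionine substitution with those of the control line. No gene passed in limma's test (0 of 29795), and 434 genes had an unadjusted p under 0.05 where 1490 are given by chance. The gene with the smallest p was Scgb1c1, a secretoglobin of secretory epithelia, at -0.57 ± 0.39 in I183M and 3.13 ± 0.74 in control (log2 fold -3.70, SE 0.42, adjusted p 0.193). Its 3 control arrays read between 2.28 and 3.62, and none of the 9 arrays of the mutant lines read above 0.22. Others with the smallest p, none of which passed, were Plekhh1 (-2.18), Slc17a7, a vesicular glutamate transporter (-1.99), Grin2c, a subunit of glutamate receptors (-2.46), Rfx8 (-2.26) and Pde3b, a phosphodiesterase of cyclic nucleotides (1.80), all with adjusted p 0.879. For probes not well above background on any I183M array, the bounds were at least 6.18-fold lower for AI593442 (adjusted p 0.393), 8.12-fold for Tlcd4, 3.98-fold for Shisa6 and 2.72-fold for Gdnf, a neurotrophic factor (adjusted p 0.879 each). The log2 folds of these 4 after normexp and quantile normalization lay below their bounds, at -0.88, -1.08, -0.70 and -0.35. Those of Plekhh1, Slc17a7, Grin2c and Rfx8 were -1.02, -0.74, -0.75 and -0.76 on that scale. Among listed genes, Nppa and Nppb, which encode the natriuretic peptides ANP and BNP, had log2 folds of -1.54 (SE 0.55) and -1.90 (SE 0.79). Myl1, a myosin light chain of fast skeletal muscle, stood at 1.88 (SE 0.48), and Ms4a1, which encodes the B cell protein CD20, at -1.15 (SE 0.47; -0.23 with normexp and quantile normalization). The groups did not overlap for 1112 genes (3.73%, where chance gives 10%), and the median fold over all genes was 0.11. With control replicate 1 left out again no gene passed, 1835 had an unadjusted p under 0.05, and Scgb1c1 stood at -4.13 (adjusted p 0.056). With normexp and quantile normalization it passed at -3.79 (adjusted p 8.2e-04), as it did in 7 of 23 alternatives, over which its adjusted p lay between 8.2e-04 and 1.

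By list, I183M versus control gave 19 of 38 lists past the threshold in camera, 17 higher and 2 lower. All 64 measured genes of oxidative phosphorylation had a fold above 0 (median 0.49, adjusted p 5.6e-13), as had all 48 of the cytosolic ribosome (median 0.48, adjusted p 1.2e-09) and 39 of 40 of fatty acid uptake and oxidation (median 0.50). Pfkfb1, which sets the level of a regulator of glycolysis, stood at 1.80 (SE 0.45) in a glycolysis list of median 0.47. Ventricular cardiomyocyte markers (median 0.51, 14 of 14 above 0), the sarcomere list (median 0.46, 41 of 45) and smooth muscle and pericyte markers (median 0.53, 14 of 14) were also higher, and lung and thymus markers were lower (median -0.43, 1 of 9 above 0). None of these calls held with an estimated correlation (smallest adjusted p = 0.587 with an estimated correlation) and none passed in fry (smallest adjusted p 0.382). No gene of the called lists passed, over all genes or adjusted over the list alone, and 2 genes of lists that were not called (Wnt ligands and receptors, skeletal muscle markers) passed when adjusted over the list alone. Control replicate 1 carried the shift: without it 4 lists passed, all lower, the median of oxidative phosphorylation was 0.05 (adjusted p 0.603), that of the ribosome 0.01 (adjusted p 0.253) and that of the lung and thymus markers 0.57 (adjusted p 0.603). The fetal and stress gene list was then among the lower ones (median -0.14, adjusted p 0.0255, adjusted p = 0.927 with an estimated correlation), while with all arrays its median was 0.21 (adjusted p 0.63). With normexp and quantile normalization 5 lists passed, 4 higher and 1 lower. The interferon response list was not called with all arrays (median 0.10, camera adjusted p 0.954). It read -0.24 and -0.12 on control replicates 2 and 3 and -0.19 to -0.10 on the I183M arrays, each gene set against its mean over all arrays.

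I183P versus control concerned the change of the same residue to proline. Abca4, a lipid transporter known from photoreceptors, was the only gene to pass: it was at least 7.30-fold lower (adjusted p 0.00667), being well above background on all 3 control arrays and on no I183P array. None of the next genes passed. Flvcr2, a transporter of the Flvcr family, was at -1.83 ± 0.27 in I183P and 0.36 ± 0.34 in control (log2 fold -2.19, SE 0.25, adjusted p 0.0671). Scgb1c1 stood at -3.64 and Plekhh1 at -3.20 (adjusted p 0.0671 each). Tlcd4 (-3.91), Shisa6 (-2.15), Slc17a7 (-2.37) and Pcp4, a calmodulin-binding protein of neurons and conduction tissue (-2.94), had adjusted p between 0.162 and 0.202. The bounds for AI593442 and Grin2c were at least 6.06-fold and 7.49-fold lower (adjusted p 0.162). Leaving out control replicate 1 gave 5 genes past the threshold, 1 higher and 4 lower, with Abca4 (adjusted p 0.0188), Flvcr2 (adjusted p 0.0341), Scgb1c1 (-4.07, 0.0208) and Plekhh1 (-3.56, 0.0237) being lower. Without control replicate 2 the count was 2, and it was 0 without control replicate 3 or without any of the 3 I183P arrays. No gene passed with the slide as a block, where Abca4 had an adjusted p of 0.0566, or within slide 1, where it was 0.75. Its log2 fold, read against a dim group, was -3.13 in both and -3.05 with all arrays. With normexp and quantile normalization Abca4 stood at -0.68 (adjusted p 0.491), below its bound, while Scgb1c1 passed at -3.73 (adjusted p 9.6e-04), as it did in 11 of 23 alternatives. On that scale Plekhh1 (-1.20), Tlcd4 (-0.93), AI593442 (-0.67), Shisa6 (-0.46), Grin2c (-0.75), Slc17a7 (-0.68) and Pcp4 (-1.15) also had smaller folds. In all, 1543 genes had an unadjusted p under 0.05 (1490 by chance, and 2431 without control replicate 1), and 3809 genes (12.8%, chance 10%) did not overlap.

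The list shifts of I183P versus control numbered 19 of 38 in camera, 18 higher and 1 lower. The interferon response list was higher: 33 of its 38 genes had a fold above 0 (median 0.49, camera adjusted p 4.1e-10, adjusted p = 0.592 with an estimated correlation), and it was the only list past the threshold in fry (adjusted p 0.0348, and 0.11 without control replicate 1). Among its members Gbp4, a guanylate-binding protein (1.32, SE 0.30), Iigp1, an immunity-related GTPase (1.19, SE 0.33), and Psmb9, a subunit of the immunoproteasome (1.03, SE 0.22), did not overlap between the groups. None of the 38 passed over all genes, and 6 passed when adjusted over the list alone. The list's median without control replicate 1 was 0.44 with 35 of 38 genes above 0 (adjusted p 6.2e-14), and with the slide as a block and within slide 1 it was 0.44 (adjusted p 2.3e-07 and 2.2e-07). Lymphocyte markers were higher too without control replicate 1 (14 of 15 above 0, median 0.49, adjusted p 3.5e-05, adjusted p = 0.26 with an estimated correlation), but were not called with all arrays (median 0.19, adjusted p 0.141). Macrophage and monocyte markers were higher as well (median 0.47, 14 of 17, adjusted p 8.4e-04, adjusted p = 0.612 with an estimated correlation), among them Cx3cr1, the fractalkine receptor (2.04, SE 0.38), and their median was 0.11 without control replicate 1 (adjusted p 0.0166) and 0.22 with normexp and quantile normalization (adjusted p 0.0783). Oxidative phosphorylation (median 0.44), the ribosome (0.41) and endothelial markers (0.53) were higher too (adjusted p = 0.612 with an estimated correlation for each), and without control replicate 1 their medians were -0.01 (adjusted p 0.363), -0.06 (lower, adjusted p 0.0166) and 0.19 (adjusted p 0.00968). Single genes of other lists with large folds, none past the threshold, were Scn4b, a sodium channel subunit (1.81, SE 0.38), Kcnip2, a potassium channel partner (-1.13, SE 0.25), Casq1, the calsequestrin of skeletal muscle (1.53, SE 0.45), Pfkfb1 (2.09, SE 0.45), Bmp7 (-1.48, SE 0.37; -0.82 with normexp and quantile normalization) and Nppb (-2.08, SE 0.79). Of all lists together, 13 genes passed when adjusted over the list alone.

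Delta versus control compared hearts with the deletion with those of the control line. A total of 22 features fell and none rose (0 higher by limma), 13 of them with a symbol, where 2191 had an unadjusted p under 0.05 (1490 by chance, and 4441 without control replicate 1). Pde5a, the phosphodiesterase that breaks down cyclic GMP, fell by 3.75 (SE 0.38, adjusted p 0.0125), from 3.61 ± 0.61 in control to -0.15 ± 0.17 in delta. Emilin3, an extracellular matrix glycoprotein, fell by 3.28 (SE 0.30, adjusted p 0.00892), Scgb1c1 by 3.17 (SE 0.42, adjusted p 0.0427), Plekhh1 by 3.08 (SE 0.38, adjusted p 0.0295) and Slc49a4, a membrane transporter, by 2.94 (SE 0.39, adjusted p 0.0427). The odorant receptor genes Olfr362 and Olfr681 fell by 2.88 and 2.73 (adjusted p 0.0295 and 0.0225) and Lcn6, a lipocalin, by 2.04 (adjusted p 0.0375). The probes of Slc49a4, Emilin3, Olfr681 and Olfr362 correlated with that of Pde5a at 0.994, 0.973, 0.961 and 0.946. These values are across the arrays outside delta, without control replicate 1. The probes were picked for a high correlation and a low fold of delta against I183P, so the values are high by choice. Lcn6 and Olfr612 were outside that choice. On the same arrays they too read highest on control replicate 2 and lowest on I183P replicate 3, as Pde5a did. It stays open whether all of these probes read separate transcripts, so their falls may not be separate changes. Olfr612 was at least 13.6-fold lower (adjusted p 0.00892), AI593442 at least 7.80-fold (adjusted p 0.0295), Abca4 at least 7.17-fold (adjusted p 0.00892) and Phxr4 at least 3.62-fold (adjusted p 0.048), with no delta array well above background. The value of Abca4 is its estimated fold. AI593442 was well above background on the 3 control arrays only. A further probe of Lcn6, well above background on all 12 arrays, had a fold of -0.23, and the further probes of Olfr612, Olfr681 and AI593442, which were dimmer, had folds of -0.36, -1.13 and -1.85.

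The number of these calls changed when single arrays were left out. Leaving control replicate 1 out gave 51 features (13 higher, 38 lower), which kept 19 of the 22. Without control replicate 2 only 1 passed, without control replicate 3 none, without delta replicate 1 none, without delta replicate 2, 5, and without delta replicate 3, 2. With the slide as a block no gene passed (adjusted p 1), with folds of -2.81 for Pde5a, -2.46 for Emilin3, -2.39 for Scgb1c1, -3.92 for Plekhh1, -2.15 for Slc49a4, -1.86 for Olfr362 and -1.75 for Olfr681, and no slide held both groups. With normexp and quantile normalization 7 of the 22 calls were kept, among 11 higher and 17 lower genes. Pde5a (-3.88), Scgb1c1 (-3.30) and Slc49a4 (-3.09) passed there with an adjusted p of 7.6e-04 each. Emilin3 (-1.58, adjusted p 0.135), Plekhh1 (-1.38, 0.372), Olfr362 (-1.26, 0.158), Olfr681 (-1.47, 0.184) and Lcn6 (-0.95, 0.46) did not, nor did Olfr612 (-1.15, 0.367), AI593442 (-0.64, 0.352), Abca4 (-0.85, 0.331) and Phxr4 (-0.45, 0.495), whose folds lay below their bounds there. Groups did not overlap for 4058 genes (13.6%, chance 10%).

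**Figure D3:**
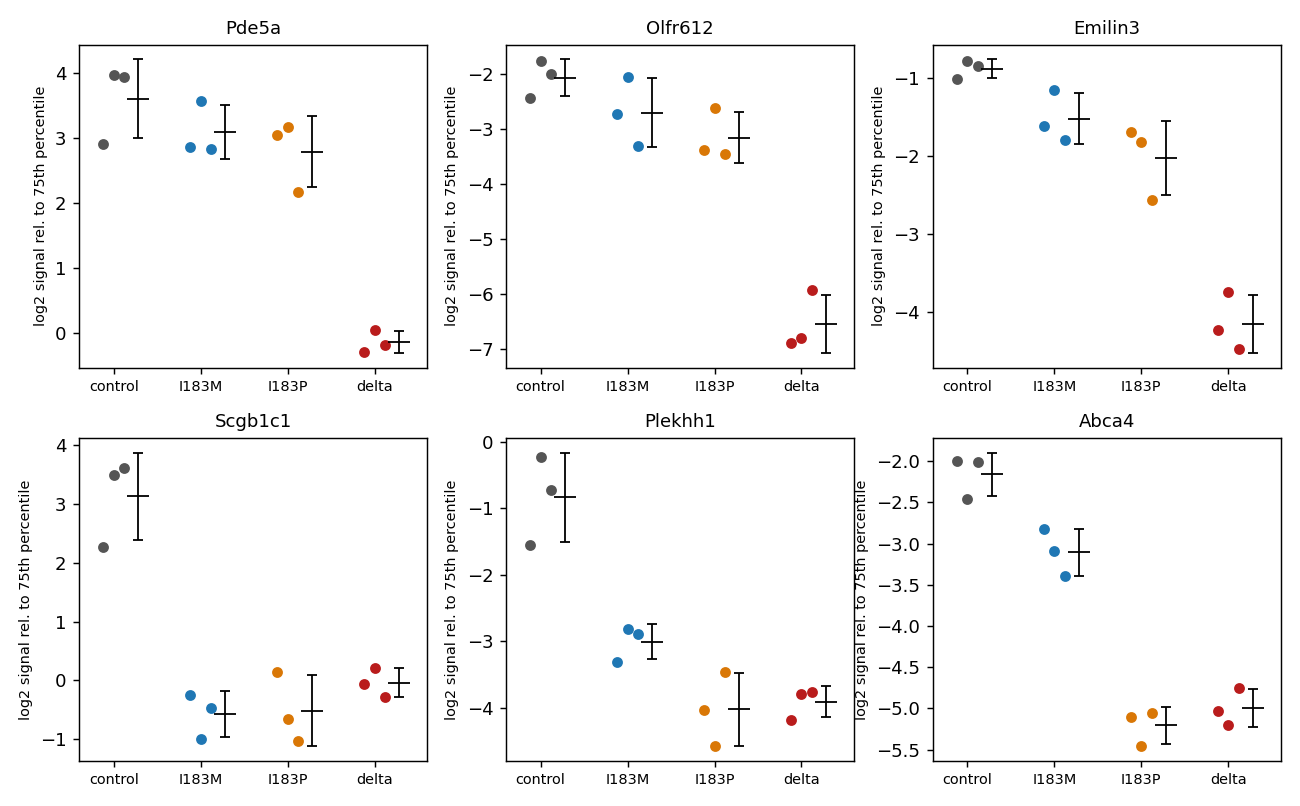
Log2 signal relative to the 75th percentile on each array (points) with group mean and SD (bars, n = 3) for Pde5a, Olfr612, Emilin3, Scgb1c1, Plekhh1 and Abca4. Pde5a, Olfr612 and Emilin3 are lowest on the 3 delta arrays (Pde5a -0.29 to 0.03), Scgb1c1 reads 2.28 to 3.62 on the control arrays and at most 0.22 on the rest, and Abca4 is lower in I183P and delta.

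Camera put 14 of the 38 lists past the threshold in delta versus control, all higher. Interferon response genes were among them (31 of 38 above 0, median 0.47, adjusted p 1.1e-07, adjusted p = 0.736 with an estimated correlation, fry adjusted p 0.0576), with Gbp4 at 1.27 (SE 0.30) and Gbp2, another guanylate-binding protein, at 1.11 (SE 0.26). Endothelial markers (17 of 18, median 0.47, adjusted p 0.00112) and macrophage markers (15 of 17, median 0.37, adjusted p 0.0406) were called higher with it (adjusted p = 0.736 with an estimated correlation for each), and their medians were 0.06 and 0.04 without control replicate 1 (adjusted p 0.761 and 0.877). Lymphocyte markers were called without that array (15 of 15, median 0.59, adjusted p 0.00299, adjusted p = 0.553 with an estimated correlation, and not with all arrays, where the median was 0.26 and the adjusted p 0.147). No gene of the interferon list passed over all genes, and 2 passed when adjusted over the list alone. Its median was 0.34 without control replicate 1 (adjusted p 5.3e-04) and 0.25 with the slide as a block (adjusted p 0.129), where Gbp4 stood at 0.46. The heat shock list (median 0.56, 37 of 39 above 0), the sarcomere list (0.50, 40 of 45), the ribosome (0.55, 48 of 48) and oxidative phosphorylation (0.53, 64 of 64) were higher, and no call held with an estimated correlation (smallest adjusted p 0.736) or in fry. Leaving out control replicate 1 gave medians of 0.18, 0.11, 0.08 and 0.07, with adjusted p 0.538, 0.957, 0.538 and 0.855, and 3 lists passed. Single list genes that did not pass were Myh7, the slow myosin heavy chain raised in stressed mouse ventricle (2.42, SE 0.69), Tpsb2, a mast cell tryptase (1.87, SE 0.40), Scn4b (1.52, SE 0.38), Cx3cr1 (1.45, SE 0.38; 0.95 with the slide as a block) and Tgfb2, a growth factor (1.11, SE 0.28). Of all lists, 4 genes passed when adjusted over the list alone.

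Direct comparison of I183P with I183M tested the difference between the substitutions. No gene passed in limma (0 of 29795, 380 with an unadjusted p under 0.05, where chance gives 1490). With control replicate 1, which is in neither group, left out of the shared fit, 2834 had an unadjusted p under 0.05 and again none passed. The smallest p belonged to Abca4, at least 3.78-fold lower in I183P (adjusted p 0.187), Fcgr4, an Fc receptor of myeloid cells (1.32, SE 0.24), and Npy1r, a receptor of neuropeptide Y (-1.85, SE 0.34, adjusted p 1 for both). Normexp and quantile normalization put Abca4 at -0.47 and Npy1r at -0.80, and Cxcl10 and Ms4a1 of the lists below at 0.83 and 0.72. The interferon response list was higher in I183P: all 38 measured genes had a fold above 0, the median was 0.39 and the camera adjusted p 5.2e-29, and the call held with an estimated correlation (adjusted p = 0.032 with an estimated correlation). This was the only call of any comparison that did. Examples were Cxcl10, an interferon-induced chemokine (1.49, SE 0.42), Gbp4 (1.15, SE 0.30) and Psmb9 (0.78, SE 0.22), whose 3 I183P arrays all lay above the 3 I183M arrays. None of the 38 genes passed, over all genes or adjusted over the list alone, and fry gave an adjusted p of 0.0907. With the slide as a block and within slide 1 the median was 0.35 (adjusted p 4.6e-19 and 4.8e-18), and without control replicate 1 in the shared fit the adjusted p was 0.103 with an estimated correlation and 0.0287 in fry. Of the other 8 lists past the threshold, lymphocyte markers were higher (12 of 15, median 0.20, adjusted p 4.3e-05), with Ms4a1 at 1.47 (SE 0.47), as were cell cycle genes (29 of 39, median 0.27, adjusted p 1.9e-06), macrophage markers (15 of 17, median 0.11, adjusted p 4.5e-04), with Cx3cr1 at 1.95 (SE 0.38), and endothelial markers (13 of 18, median 0.17, adjusted p 0.00188), with Cldn5, a tight junction protein, at 1.15 (SE 0.35). The adjusted p values with an estimated correlation were 0.546 for lymphocyte, cell cycle and macrophage lists and 0.963 for endothelial markers. The macrophage median was 0.17 without I183M replicate 2 and 0.19 without I183P replicate 2.

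In the same comparison adipocyte markers were lower (3 of 12 above 0, median -0.89, adjusted p 0.00431, adjusted p = 0.546 with an estimated correlation), with Cfd, the adipokine adipsin, at -2.09 (SE 0.82). Without I183P replicate 3, which also gives the value with the slide as a block, that median was -0.58 (adjusted p 0.159), and the median of the cell cycle list was 0.13 (adjusted p 0.002). The latter was 0.17 without I183M replicate 2, and the adipocyte median was -0.24 with normexp and quantile normalization. Erythroid markers were higher (9 of 9, median 0.25, adjusted p 0.00199, adjusted p = 0.963 with an estimated correlation), with a median of 0.19 with the slide as a block and without I183P replicate 3 (adjusted p 0.0583), and 0.40 without I183P replicate 2. The call of cardiac transcription factors (16 of 29, median 0.09, adjusted p 0.0188, adjusted p = 0.963 with an estimated correlation) ended without I183M replicate 1 (median 0.01, adjusted p 0.299), without I183P replicate 1 (0.02, 0.23) and with normexp and quantile normalization (0.08, 0.418). Extracellular matrix genes were called higher with a median of 0.05 and a mean of -0.04, so that the test and the mean differ in sign. The sign of median, mean or test differed for 21 of the 38 lists here, and for 4, 5, 2, 7 and 14 lists in I183M, I183P and delta versus control, delta versus I183M and delta versus I183P. Groups did not overlap for 7267 genes (24.4%, chance 10%).

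Delta versus I183M also gave 0 genes past the threshold in limma (1045 with an unadjusted p under 0.05, where chance gives 1490). With control replicate 1 left out of the shared fit, 3410 had an unadjusted p under 0.05. Emilin3 (-2.63, SE 0.30), Pde5a (-3.24, SE 0.38) and Olfr612 (at least 8.76-fold lower) had the smallest p (adjusted p 0.0764 each), and with control replicate 1 left out of the shared fit all 3 were lower past the threshold (adjusted p 0.0366, 0.0221 and 0.0302), among 13 genes in all. The log2 folds after normexp and quantile normalization were -3.02 for Pde5a, which passed there (adjusted p 0.00904), -1.44 for Emilin3 (0.354) and -1.04 for Olfr612 (0.687), and those of Cxcl10, Ms4a1 and Upk3b, named below, were 0.76, 0.89 and 0.99. The fetal and stress gene list was higher (22 of 26 above 0, median 0.30, adjusted p 0.00142, adjusted p = 0.986 with an estimated correlation), with Nppa at 1.94 (SE 0.55), Nppb at 2.08 (SE 0.79) and Myh7 at 1.55 (SE 0.69), which stood at 2.30, 0.68 and 0.75 with the slide as a block. Delta replicate 3 read highest for Myh7 (8.22), and without that array the list's median was 0.19 (adjusted p 0.286). The same median was 0.60 without I183M replicate 1, 0.17 without I183M replicate 3 and 0.57 without delta replicate 2. Interferon response genes were higher (35 of 38, median 0.34, adjusted p 4.6e-15, adjusted p = 0.22 with an estimated correlation), with Cxcl10 at 1.53 (SE 0.42) and Gbp4 2.15-fold higher, but with the slide as a block the median was 0.16 (adjusted p 0.0684) and Gbp4 stood at a log2 fold of 0.29. Lymphocyte markers were higher (12 of 15, median 0.32, adjusted p 2.3e-04, adjusted p = 0.476 with an estimated correlation; 0.35 with the slide as a block, adjusted p 0.0131), with Ms4a1 at 2.08 (SE 0.47). Mesothelial and epicardial markers were higher too (10 of 11, median 0.44, adjusted p 4.6e-04, adjusted p = 0.299 with an estimated correlation), with Upk3b, an uroplakin of the mesothelium, at 2.25 (SE 1.09) and Msln, mesothelin, at 1.89 (SE 0.79), which stood at 4.86 and 4.87 with the slide as a block. Their median was 0.92 without I183M replicate 1, 0.85 with the slide as a block and 0.27 with normexp and quantile normalization. In this comparison the slide could be estimated only from I183P replicate 3 against I183P replicates 1 and 2. The mesothelial list read lowest of all arrays on replicate 3 (-1.07), and Nppb read 3.70 on it against 2.33 and 2.27. All values with the slide as a block given here therefore rest on that array. Tpsb2 stood at 1.77 (SE 0.40). In all, 6 lists passed in camera, 5 higher and 1 lower. Non-overlapping groups were found for 5155 genes (17.3%, chance 10%), and 2 list genes passed when adjusted over the list alone.

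Delta versus I183P compared the deletion with the proline substitution. No gene passed in limma (828 with an unadjusted p under 0.05), and the smallest p belonged to Olfr612 (at least 6.40-fold lower in delta, adjusted p 0.262), Pde5a (-2.94, SE 0.38, adjusted p 0.265) and Emilin3 (-2.13, SE 0.30, adjusted p 0.341). Within slide 2, which held 1 I183P array, Pde5a stood at -2.31 and Emilin3 at -1.59 (adjusted p 0.917 each). With control replicate 1 left out of the shared fit 7 genes passed, 3 higher and 4 lower, and Pde5a was among the lower (adjusted p 0.0341). In that fit 3588 genes had an unadjusted p under 0.05, where chance gives 1490. After normexp and quantile normalization Pde5a passed at -2.74 (adjusted p 0.0327), and Emilin3 stood at -1.19 and Olfr612 at -0.97 (adjusted p 0.855 and 0.987). Mesothelial and epicardial markers were higher in delta: all 11 had a fold above 0 (median 1.22, adjusted p 1.4e-04, adjusted p = 0.406 with an estimated correlation), among them Msln (1.84, SE 0.79) and Krt18, a keratin of simple epithelia (1.03, SE 0.30). Their median of 1.51 within slide 2 and with the slide as a block rests on I183P replicate 3 alone, the array on which the list read lowest, and so do values of 3.83 for Msln and 1.33 for Nppb. With normexp and quantile normalization the median was 0.39 (adjusted p 5.4e-05). With all arrays the size of the difference depended on I183P replicate 3 too. The list read -0.18, -0.02 and -1.07 on I183P replicates 1, 2 and 3 and 0.37 to 0.78 on the delta arrays. Cell cycle genes were lower (12 of 39 above 0, median -0.22, adjusted p 1.1e-05, adjusted p = 0.837 with an estimated correlation), and their median was -0.47 with the slide as a block, which rests on I183P replicate 3 as well. It was -0.49 and -0.14 without I183P replicates 1 and 3, and -0.34, -0.35 and -0.10 without delta replicates 1, 2 and 3. Extracellular matrix genes were lower (13 of 48, median -0.17, adjusted p 5.1e-04, adjusted p = 0.863 with an estimated correlation), with a median of -0.28 without delta replicate 1 and -0.13 without delta replicate 2 (adjusted p 0.242). The median of the fibroblast markers was 0.08 to 0.24 on the I183P arrays and -0.21 to 0.19 on the delta arrays. That of the smooth muscle and pericyte markers was 0.16 to 0.30 and -0.09 to 0.14, each gene set against its mean over all arrays. Hspa1a, an inducible heat shock protein, stood at 2.64 (SE 0.84), Nppb at 2.26 (SE 0.79), Tpsb2 at 1.54 (SE 0.40) and Angptl4, an inhibitor of lipoprotein lipase, at -1.38 (SE 0.48). Altogether 9 lists passed, 2 higher and 7 lower, 5786 genes did not overlap (19.4%, chance 10%), the median fold over all genes was 0.14, and 1 list gene passed when adjusted over the list alone.

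**Figure D4:**
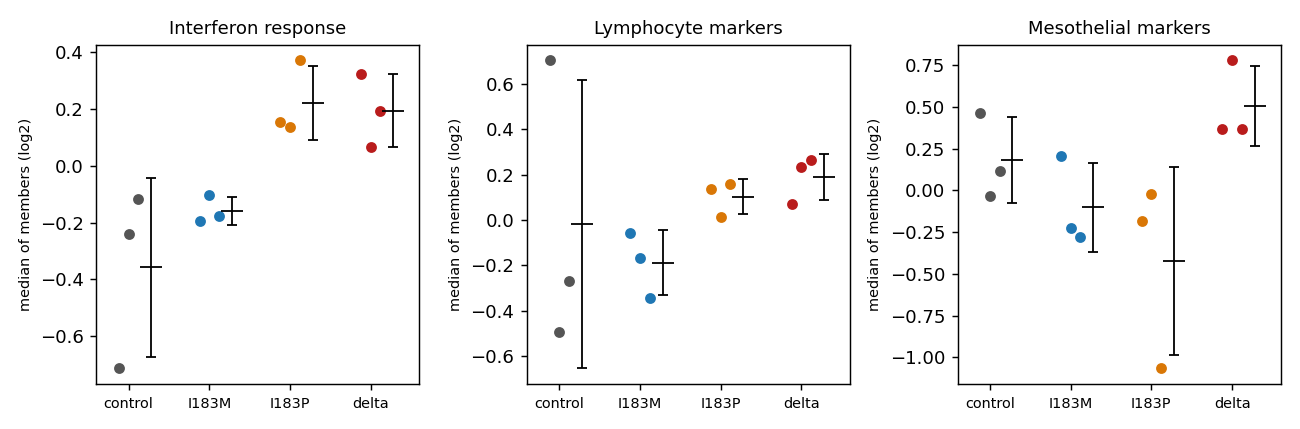
Median log2 value of the members of the interferon response, lymphocyte and mesothelial lists on each array (points), each gene relative to its mean over all arrays, with group mean and SD (bars, n = 3). The interferon list reads 0.14 to 0.37 on the I183P arrays and -0.19 to -0.10 on the I183M arrays, and the mesothelial list reads -1.07 on I183P replicate 3 and 0.37 to 0.78 on the delta arrays.

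Genes of the fetal and stress program and of the atria varied between arrays of the same group. Nppb read 1.99 and 2.05 on I183M replicates 2 and 3 and 2.33 and 2.27 on I183P replicates 1 and 2, against 4.80 on I183M replicate 1, 3.70 on I183P replicate 3, 4.01 to 5.36 in control and 4.48 to 5.93 in delta. Sln, the atrial inhibitor of the calcium pump, ranged from -3.24 on control replicate 2 to 5.41 on delta replicate 1. Myl7, the atrial myosin light chain, ranged from -5.06 on I183P replicate 3 to 4.13 on delta replicate 1, and Myl4, the other atrial light chain, from 1.03 to 6.72 on the same arrays. The atrial marker list passed in no comparison: its median was 0.25 in I183M, 0.27 in I183P and 0.28 in delta versus control (camera adjusted p 0.988, 0.53 and 0.284).

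**Figure D5:**
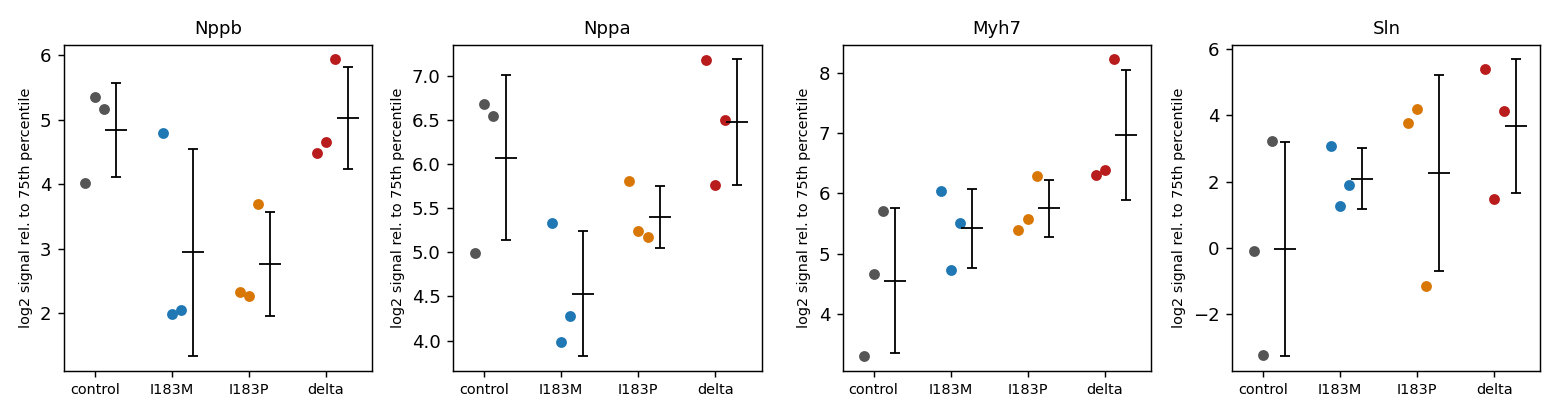
Log2 signal relative to the 75th percentile of Nppb, Nppa, Myh7 and Sln on each array (points) with group mean and SD (bars, n = 3). Sln spans -3.24 to 5.41 with a wide spread inside groups, and Myh7 is highest on delta replicate 3 (8.22).

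Shared changes of the mutant lines were read from the 3 comparisons with the same control arrays. No gene passed in all 3 comparisons in 1 direction, and Abca4 was the only gene to pass in 2 of them, being lower in I183P and delta, which were compared with the same 3 control arrays. Scgb1c1 was lower past the threshold in all 3 comparisons with normexp and quantile normalization (-3.79, -3.73 and -3.30, adjusted p 8.2e-04, 9.6e-04 and 7.6e-04), and Abca4 passed in none of them there. Direct tests of Abca4 put I183P below I183M at an adjusted p of 0.187. Across genes, which are not independent replicates, the log2 folds correlated at 0.556 for I183M and I183P, 0.561 for I183M and delta, and 0.695 for I183P and delta, while simulated unchanged groups against the same controls gave 0.833, 0.833 and 0.833. The observed covariances of 0.243, 0.167 and 0.384 lay below the simulated 0.888, 0.887 and 0.888. Unchanged groups that share the controls should not give far larger covariances than the real groups do. The simulated spread may therefore not match that of these arrays, and the simulated values, also those that follow, are a weak reference. Without control replicate 1 the correlations were 0.350, 0.743 and 0.399 (simulated 0.302, 0.303 and 0.302), and the covariances exceeded the simulated ones by 0.048, 0.310 and 0.047. The 3 control arrays cannot be split into parts of 2, so part of any excess may come from the shared controls. The pair with the largest excess, I183M and delta, holds I183M replicate 1 and delta replicate 2. These arrays had the next highest signal of dim probes after control replicate 1 (3.68 and 3.36). Whether they carry the excess was not tested. In pairs of comparisons that share no array the correlation was 0.298 for I183P versus control with delta versus I183M, -0.242 for I183M versus control with delta versus I183P, and 0.473 for delta versus control with I183P versus I183M. These pairs still share the slides, which differ between the groups in both comparisons of the first pair and of the last pair.

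Of the 432 genes tested within 10 Mb of Nkx2-5 on its chromosome, none passed in any of the 6 comparisons by limma. At an unadjusted p under 0.05 there were 1, 27 and 26 of them in I183M, I183P and delta versus control, or 0.232%, 6.25% and 6.02%, against 1.48%, 5.16% and 7.37% of all other genes (two-sided Fisher's exact p 0.0240, 0.323 and 0.352). For I183M the same test gave p 0.388 and 0.230 in windows of 5 and 20 Mb. Without control replicate 1 the counts within 10 Mb were 20, 45 and 61 (Fisher's exact p 0.225, 0.0919 and 0.683). In the 20 Mb window without that array the Fisher's exact p of I183P was 0.0159. The test treats neighbouring genes as independent, which they need not be.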

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

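All tests in this part were chosen after the results were seen, except the test for lymphocytes and the other splits of the arrays.

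The interferon response list stood 0.392 higher in I183P than in I183M, by a direct test of the difference, with 38 of 38 genes above 0, and delta stood 0.343 above I183M (adjusted p = 0.22 with an estimated correlation). No single gene of the list passed, fry gave an adjusted p of 0.0907 for I183P versus I183M, and its call with an estimated correlation (0.032) was lost without control replicate 1 (0.103), where fry passed (0.0287). The tables argue against the scaling of the arrays as the source, since over 5 scalings and both comparisons the smallest median was 0.291, and against the slide for the I183P part, since within slide 1 the median was 0.350 and 29 of 38 genes read higher on I183P replicates 1 and 2 than on all 3 I183M arrays. For the delta part the slide stays open: with the slide as a fixed block the median was 0.158 (adjusted p 0.0684, 25 of 38 above 0), and delta and I183M shared no slide. More lymphocytes in the tissue piece stay open too, because the lymphocyte markers' median of 0.198 minus the list's gave -0.193, with a bootstrap standard error of 0.157. A difference between the lines may underlie the I183P part and was tested only on the data in which it was found.

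Control replicate 1 gave signal in spots that the comparisons do not use: its negative-control spots had a raw median of 97, against 47 to 63 on the other arrays, and its probes that were dim elsewhere had a median log2 intensity of 7.74. Staining that does not depend on the probe's sequence is argued against, since the negative-control spots rose by a ratio of only 0.177 of the rise of the dim probes. Genomic DNA in the labelled sample is argued against for a male animal, as probes on the X chromosome would rise less than autosomal ones, while the difference of the medians was -0.041 (bootstrap interval -0.116 to 0.074). A cause acting on the whole slide or its scan would reach the other arrays of the slide, and 0 of these 7 came within 4-fold. That count was already fixed when this array was picked for standing apart. It does not cover a cause confined to this array. What raised the signal stays open, and no biological explanation was tested.

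With 3 against 3 arrays there are 10 splits of the 6 arrays, too few for a share under 0.05. Splits that called at least as many genes as the real one, the real one included, numbered 10, 2 and 1 for I183M, I183P and delta versus control, with 0, 1 and 22 genes in the real split and at most 8, 5 and 2 in the others. For I183P versus I183M, delta versus I183M and delta versus I183P the number was 10 each, with 0 genes in every split. For gene lists the numbers were 8, 7 and 9 against control, with 19, 19 and 14 lists in the real split and at most 20, 23 and 25 in the others. For the direct comparisons they were 5, 9 and 7, with 9, 6 and 9 lists in the real split and at most 21 in the others of each. A split of the I183M and control arrays called 8 genes where the real one called 0. Whether a structure of the samples other than the groups gave these calls was not tested.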

How the results depend on the processing

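Alternatives that left control replicate 1 out of the direct comparisons or the shared changes, left it out together with another choice, left out 3 arrays or added a covariate were chosen after the data were seen, as were those for the direct list tests, and the others before. Over 88 pairs of a named gene and a comparison, 1996 alternatives were run: 1715 kept direction and side of the threshold, 161 lost the threshold, 113 passed only in the alternative and 7 changed sign, apart from Nkx2-5 against control, which is given below. Counts below are given against 0, 1 and 22 genes for I183M, I183P and delta versus control, 0 in each direct comparison, and 19, 19 and 14 lists against control. The cause was not tested unless stated.

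Nkx2-5 in I183P versus I183M (0.02) had these 7 changes of sign: -0.02 with normexp and quantile normalization, with and without control replicate 1, -0.03 in the authors' table, -0.002 without I183M replicate 1 and -0.048 without I183P replicate 1 (between -0.048 and 0.066 without single arrays), -0.002 without the 3 arrays with raised signal of dim probes, and -0.141 with that signal as a covariate. For delta versus control the fold of Nkx2-5 lay between -0.68 and 0.04 without single arrays, the last without control replicate 3 (0.044). It passed with normexp and quantile normalization (-0.724, adjusted p 0.0286), also without control replicate 1 (-0.71, adjusted p 0.0139), and its adjusted p was otherwise above the threshold. Without single arrays its fold was 0.07 to 0.79 in I183M and 0.09 to 0.82 in I183P versus control.

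Normexp and quantile normalization gave 2 and 3 genes for I183M and I183P versus control, 5 for delta versus I183M and 4 for delta versus I183P, and 5, 8 and 1 lists against control. For delta versus control it gave 28 genes, 11 of them higher where the reported 22 were all lower. Quantile normalization gave 1 gene for I183M and 11 for delta versus control (1 higher, 10 lower), 4 for delta versus I183M and 2 for delta versus I183P, and 8, 9 and 1 lists. Median scaling gave 3 genes for I183P versus control and 5 for delta versus I183M. The authors' table gave 2 and 2 genes for I183M and I183P versus control, 5 for delta versus I183M and 3 for delta versus I183P, and 3, 8 and 1 lists.

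With no filter on dim probes 13 genes passed in delta versus control, where 37029 genes were tested in place of 29795. With probes well above background on all 12 arrays, 1, 3 and 45 genes passed against control (20 higher and 25 lower in delta), 19 for delta versus I183M and 7 for delta versus I183P, and 10, 10 and 5 lists. Signal over background limits which genes can be read, as 25125 probes were above it on all 12 arrays. Fitting every probe by itself changed none of the counts by over 1.5 times.

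With the slide as a fixed block 0 genes passed in I183P and in delta versus control, 11 lists in delta versus I183M (reported 6), and 0 shared changes. The slide as a random block gave 306 genes for delta versus control (200 higher, 106 lower) and 38 for delta versus I183M, at an estimated slide correlation of -0.132. A negative correlation lowers the SE of groups on different slides, so these counts are not corrected for the slide. Within slide 1, 0 genes passed for I183P versus control, and within slide 2 delta versus I183P gave 0 as before. Slide 2 held no control or I183M array.

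The deviations of same-numbered arrays from their group means correlated over 0.1 in 6 of 18 pairs, among them the 3 pairs of I183M and control (0.79, 0.558 and 0.502), and the lowest was -0.814. Deviations from a mean of 3 arrays depend on one another, so those 3 pairs are not separate observations. Control replicate 1 and I183M replicate 1 were also the arrays with the highest signal of dim probes. As a hint from the data, 3 of 12 arrays correlated best with an array of their own number, so the numbers were not taken as pairs. With the replicate number as a block 7 genes passed for delta versus control, and for I183M versus control 0 genes and 17 lists passed.

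Fits of only the 2 groups compared gave 0 genes for I183P and 0 for delta versus control, with fewer residual degrees of freedom. With trend and robust, eBayes gave 1, 4 and 53 genes against control (26 higher and 27 lower in delta), 22 for delta versus I183M and 9 for delta versus I183P. Array weights gave 21, 113 and 77 genes against control, 1985 for I183P versus I183M, 423 for delta versus I183M and 35 for delta versus I183P. The weight of control replicate 1 was 0.0120 and that of I183M replicate 3 was 6.79.

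An estimated correlation in camera left 0, 0 and 0 lists against control and 1, 0 and 0 in I183P versus I183M, delta versus I183M and delta versus I183P. Leaving control replicate 1 out as well left 0, 0 and 0 against control. In fry 0, 1 and 0 lists passed against control.

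Without single arrays, 0 to 5 genes passed for I183P versus control and 0 to 51 for delta versus control, the highest without control replicate 1. For I183M versus control and the direct comparisons no gene passed without any single array of theirs. Lists numbered 4 to 20, 7 to 21 and 3 to 19 against control, the lowest without control replicate 1 in each.

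With control replicate 1 left out of the shared fit 13 genes passed for delta versus I183M, 7 for delta versus I183P, and 15 lists for delta versus I183P (reported 9). With the 3 arrays left out, 4, 0 and 0 genes passed against control, 7 for I183P versus I183M and 7 for delta versus I183M, and 2, 9 and 2 lists against control and 5 for delta versus I183P. Normexp and quantile normalization without control replicate 1 gave 10, 11 and 298 genes against control (145 higher and 153 lower in delta), 90 for delta versus I183M and 10 for delta versus I183P, and 0, 8 and 2 lists. The signal of dim probes as a covariate gave 5 genes for I183P and 80 for delta versus control (33 higher, 47 lower), 23 for delta versus I183M and 8 for delta versus I183P. The slide as a block without control replicate 1 gave 7 genes for I183P and 0 for delta versus control, and 3, 4 and 7 lists.

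Shared changes (reported 1) numbered 3 with normexp and quantile normalization, 4 with control replicate 1 left out and 0 in pairs of comparisons that share no array. The correlation of log2 folds of I183M and I183P (reported 0.556) was 0.866 with normexp and quantile normalization and 0.350 with control replicate 1 left out. That of I183M and delta (reported 0.561) was 0.765 and 0.743 in these, and that of I183P and delta (reported 0.695) was 0.399 with control replicate 1 left out. The count of genes near Nkx2-5 was 0 in windows of 5 and 20 Mb. Another probe of Nkx2-5 was not run, as there was 1 probe.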

Other observations

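The tests in this part were chosen after the result was seen, and so were the genes named here outside the rule.

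Delta replicate 3 read highest of all 12 arrays for Timp1, Hmox1, Myh7 and Nppb, which were picked because they stood out on it. Timp1, an inhibitor of matrix proteases, read 1.77 there and at most 0.76 on the others, and Hmox1, the heme oxygenase induced by oxidative stress, read 2.70 against at most 1.36. Myh7 read 8.22 and Nppb 5.93, and no list of such genes was tested for this array.

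Atrial and mesothelial genes were low together on I183P replicate 3. Myl7 read -5.06 and Myl4 1.03 on it, the lowest of all arrays, and Sln read -1.14 against 3.76 and 4.19 on I183P replicates 1 and 2. The mesothelial list was at -1.07 on this array and at -0.18 and -0.02 on the other I183P arrays. Atrial and mesothelial readings did not go together everywhere, since control replicate 2 had the lowest Sln of all arrays (-3.24) and a mesothelial median of -0.04.

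A set of 16 features was lower together in delta, among them Pde5a, Emilin3, Olfr681, Olfr362 and Slc49a4. The set was defined from the data, by a high correlation with Pde5a on the arrays outside delta and a low fold of delta against I183P. Of its features, 6 had a symbol and 11 had a known chromosome, on 8 chromosomes. The median was at a log2 fold of -1.999 against I183P, a low value that the definition of the set fixed in advance. Of the known chromosomes, 0 of 11 were that of Nkx2-5, which leaves sequence linked to the targeted locus open as long as the probes may read a sequence from elsewhere. That 1 sequence was read by all of these probes stays open, as only 1 other probe of the same genes was tested (Olfr681, 0.607). The slide that holds the delta arrays may also contribute, since I183P replicate 3, on the same slide, differed from replicates 1 and 2 by -0.931 at the median, and the loss of an allele as a biological explanation stays untested beside these.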
